A study of Homo sapiens with 4 samples.

How the data were processed

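Total RNA of MOLM-14 cells was extracted with a column kit that also keeps small RNA, and biotin-labelled sense target was made with an Affymetrix whole-transcript kit, per the labels' protocols. The 2 groups of 2 arrays each, control and DZNep, and the replicate numbers come from the sample titles, and the sample descriptions name DMSO as the control treatment. The deposited table gives 1 intensity per probe set and array on a linear scale, summarised by the authors with RMA, per the submitters' processing notes. The RMA version, software and probe set level are not given in the sources used here. The lowest deposited intensity was between 18.1 and 18.5 on every array and the highest between 14594 and 16502, with no missing value, no repeated probe set and 0 columns left unused. A floor near 18 could come from a constant added before or after summarising, and whether one was added stays unknown. Such a constant would make folds of dim genes too small.

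The fit was planned for log2 values, with log2 to be taken if the values proved linear, which they did, so log2 of the deposited intensity was taken with no pseudocount and no further normalization. Probe sets were named only through the platform annotation supplied with the series, which can be old. Of 28869 probe sets, 19310 have 1 gene symbol, 1752 have several and 7807 are not listed there. The entrez IDs of 19279 of the named ones were found in the RefSeq gene table and changed 0 symbols. A gene is represented by its probe set with the highest mean log2 over the 4 arrays among those with 1 symbol, which gave 18377 genes, 685 of them with more than 1 probe set. No dim gene was removed.

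Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The fit had 2 residual degrees of freedom per gene and 7.18 prior degrees of freedom. An exact permutation test of a single gene with 2 arrays against 2 cannot give a p under 0.333, so calls rest on limma's pooling of the spread across genes. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 35 lists. The lists, with 994 entries, were drawn up from general knowledge of the cell type and the drug before the data were examined, and 895 entries were measured. A further 31 lie only in probe sets with several symbols and 68 have no named probe set here, HOXA9 among them. Counts of list members past the threshold are given over all genes and adjusted over the list alone. Camera with an estimated correlation and fry were run beside it.

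The genes named were fixed by rule before the data were examined. They are the 10 largest rises and 10 largest falls among called genes whose arrays separate, 10 genes of interest (TXNIP, EZH2, EED, SUZ12, AHCY, FBXO32, CDKN1A, HOXA9, MEIS1 and MYC), and from each list up to 4 called members with the largest change, or up to 2 where none passed. The rule gave 126 measured genes. Genes and gene families outside it are said to have been chosen after their values were seen.

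The script was tested on simulated data built from the fitted values of the DZNep and DMSO comparison, in 20 simulations of 18377 genes with 200 changed genes each. With gene variances drawn from the fitted prior, it recovered 34.0% of changes of 0.5, 98.4% of changes of 1 and 100% of changes of 2 on the log2 scale, and 4.8% of calls were false. With each gene's own moderated variance in place of that, it recovered 82.0% of changes of 0.5 and 100% of the larger ones, and 7.41% of calls were false. Far more genes were called in the data (1892) than were changed in a simulation, and the Benjamini-Hochberg cutoff depends on that number. The shares recovered need not hold for the real comparison. A shift of −0.3 put on the mitosis list was called by camera in 20 of 20 simulations, and 0 of 660 unshifted lists were called. The simulated genes varied independently of one another, so these runs cannot show how often camera errs when genes of a list vary together. In the data the estimated correlation was 0.60 for the mitosis list and 0.73 for the unfolded protein response list.

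Alternatives set before the data were examined were the replicate number as a block, filters on the dimmest 25% and 50% of genes, median centring, quantile and cyclic loess normalization, an intensity trend with and without robust hyperparameters, array weights, the mean over a gene's probe sets, a test of every probe set, treat against a 1.5-fold change, fry, camera on ranks and with an estimated correlation, and leaving out each array in turn. Subtracting 16 from every intensity before log2 and a crossed replicate block were added after seeing the data. Without 1 array, a group holds 1 sample, which is assumed to vary like the other group. Without either DZNep array, named genes with equal changes had equal adjusted p whatever their own spread (JUN and APAF1, both at 0.465 without DZNep replicate 1). In effect these fits used a common spread for all genes. A call that passed or ended there reflects the size of its change against that spread, and need not show that it rested on that array. Figures were drawn with matplotlib 3.10.9.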

Results

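The series measured gene expression in MOLM-14 cells, an established human acute myeloid leukemia line with monocytic features, on 4 Affymetrix whole-transcript arrays. The solvent DMSO was given to 2 samples and DZNep at 2 µM to 2 samples, and all 4 were collected after 24 h. DZNep, 3-deazaneplanocin A, blocks S-adenosylhomocysteine hydrolase, the enzyme that clears the by-product of methyltransferase reactions, and is used to deplete EZH2, the histone H3 lysine 27 methyltransferase of Polycomb repressive complex 2 (PRC2). The labels call the 4 samples biological replicates and do not say whether they were separate cultures, so p-values measure only the spread between these samples, which may be technical. The median log2 intensity over all probe sets was 6.99 and 7.07 on the DMSO arrays and 7.08 and 7.05 on the DZNep arrays. The SD of the log2 difference over 18377 genes was 0.20 between the DMSO arrays, 0.14 between the DZNep arrays, and 0.27 to 0.32 between a DMSO and a DZNep array. The number of arrays limits the precision of every value below.

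In the DZNep samples most genes of the amino acid and endoplasmic reticulum stress responses were lower, by the widest margin of all lists, most DNA replication genes were lower, and TXNIP and some monocyte and inflammatory genes were higher than with DMSO. DDIT3, the stress-induced transcription factor CHOP, fell from a log2 intensity of 11.41 ± 0.22 to 7.57 ± 0.19 (SD, n = 2 arrays each), 14.4-fold lower (limma, log2 fold change −3.85, SE 0.13, adjusted p = 4.66e-06). TXNIP, the thioredoxin-interacting protein, rose from 10.46 ± 0.05 to 12.75 ± 0.10, 4.90-fold higher (limma, log2 fold change 2.29, SE 0.10, adjusted p = 7.4e-06). The comparison asks which transcripts differ between DZNep and its solvent, and 665 genes were higher and 1227 lower with DZNep at an adjusted p of 0.05 (limma), 10.3% of the genes tested. At least 2-fold changes were found for 59 of the higher and 121 of the lower genes. Over all genes tested, called or not, both DZNep arrays lay beyond both DMSO arrays for 49.7%, against 33.3% by chance. Without DZNep replicate 2 the count of higher genes was 336, and without DZNep replicate 1 the counts were 439 higher and 734 lower.

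**Figure D1:**
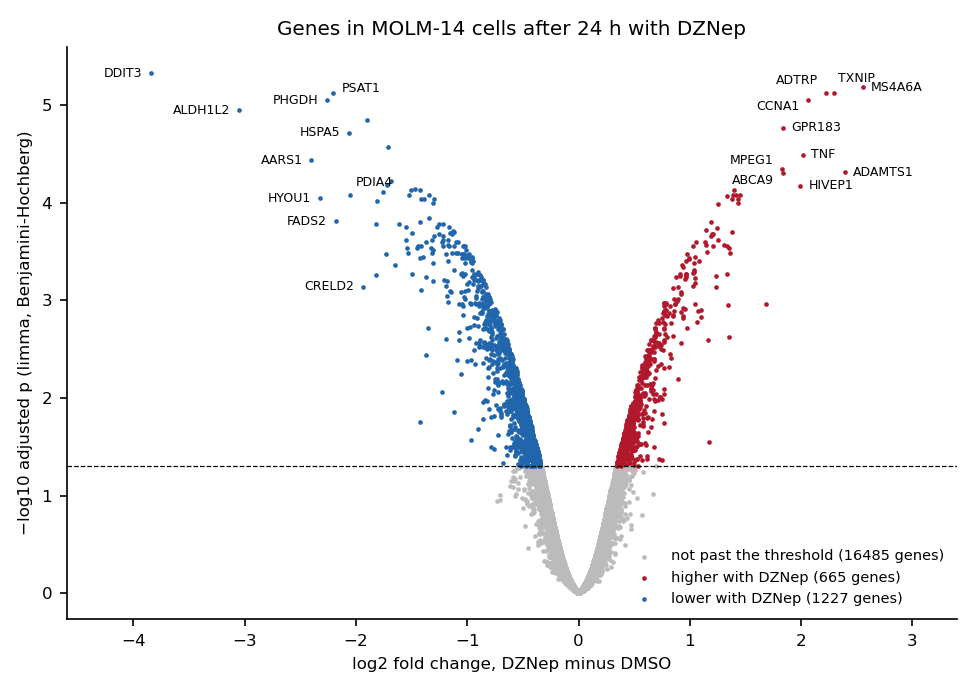
Each point is 1 of 18377 genes, with its log2 fold change (DZNep minus DMSO, 2 arrays each) on the x axis and −log10 of its limma adjusted p on the y axis; the dashed line marks an adjusted p of 0.05 and the 10 largest rises and falls are named. Points left of 0 reach further, down to −3.85 for DDIT3, than points on the right, which end at 2.55 for MS4A6A.

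The largest rises beside TXNIP were in genes of varied function. MS4A6A, a membrane protein of monocytes and macrophages, rose 5.86-fold, from 8.41 ± 0.11 to 10.96 ± 0.02 (SD, n = 2 arrays each). ADAMTS1, a secreted metalloproteinase, had a log2 fold change of 2.39, ADTRP, a membrane hydrolase, one of 2.22, and CCNA1, the cyclin A form of germ cells and some leukemias, one of 2.06. The cytokine TNF rose by 2.02, a value its 3 probe sets shared. Their mean log2 intensities were also near-equal, at 8.34 to 8.35, so they may not be independent measurements. HIVEP1, a zinc finger transcription factor, rose by 1.99, GPR183, an oxysterol receptor, by 1.83, ABCA9, a lipid transporter, by 1.83, and MPEG1, the macrophage pore-forming protein perforin-2, by 1.83. Standard errors of these genes were between 0.09 and 0.15, and their limma adjusted p lay between 6.56e-06 and 6.65e-05.

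EZH2 itself fell 1.69-fold, from 9.68 ± 0.03 to 8.92 ± 0.11 (SD, n = 2 arrays each), with a log2 fold change of −0.76 (limma, SE 0.10, adjusted p = 0.0016). The other core PRC2 subunits did not pass the test, with a log2 fold change of −0.30 (limma adjusted p = 0.079) for SUZ12 and 0.05 (adjusted p = 0.842, and a value of −0.02 without DMSO replicate 2) for EED. AHCY, which encodes the enzyme that DZNep blocks, had a log2 fold change of −0.43 and missed the threshold (limma adjusted p = 0.0505), which it passed under quantile (0.0454) or cyclic loess (0.0471) normalization and, like SUZ12 (0.007), with an intensity trend (0.0081). Its value was −0.58 without DMSO replicate 2 (limma adjusted p = 0.0126) and −0.27 without DMSO replicate 1 (0.128). Of the 11 PRC2 genes measured, 1 rose and 2 fell (2 and 4 adjusted over the list alone). The accessory subunit JARID2 rose by 0.42 and the histone-binding subunit RBBP7 had a log2 fold change of −0.43. Both calls ended when either DZNep array was left out, with values of 0.43 and 0.41 for JARID2 and −0.41 and −0.44 for RBBP7. The call of RBBP7 also ended without DMSO replicate 2, at −0.33, and under quantile (limma adjusted p = 0.0557) or cyclic loess (0.0584) normalization. Among 16 genes of PRC1, the other Polycomb complex, 1 fell (1 adjusted over the list alone), SCMH1 at −0.63. Of 34 other histone, DNA and protein methyltransferases, 2 rose and 6 fell (3 and 8 adjusted over the list alone), with SETDB2, a lysine methyltransferase, at −0.59. The maintenance DNA methyltransferase DNMT1 had −0.48, a call that ended without DZNep replicate 2 (limma adjusted p = 0.11). Of 20 demethylases, 1 fell and none rose (0 and 0 adjusted over the list alone), the histone demethylase KDM1A at −0.38, a call that ended without DMSO replicate 1 or either DZNep array (limma adjusted p of 0.0918 to 0.425). None of these 4 lists shifted as a whole, with camera adjusted p of 0.285 for PRC2, 0.523 for PRC1, 0.493 for methyltransferases and 0.802 for demethylases, and the median of the demethylases changed sign, to 0.02, under quantile normalization. The demethylases passed without DMSO replicate 2 (camera adjusted p = 0.0432, median −0.12).

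**Figure D2:**
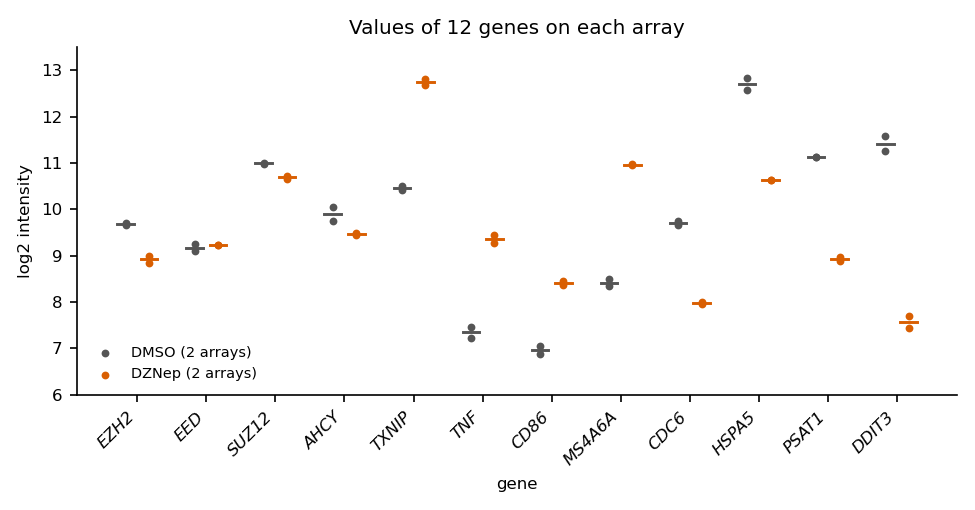
The log2 intensity of 12 genes (y axis) is shown on each of the 4 arrays, with points for single arrays and a bar for the mean of each group. EED overlaps between the groups, while EZH2 drops from 9.68 to 8.92 and DDIT3 from 11.41 to 7.57.

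Few of the genes tied to EZH2 silencing in earlier work rose, though a larger share than the 665 of 18377 in the whole test. Of 26 such genes measured, 3 rose and none fell (3 and 0 adjusted over the list alone), and the list's median log2 fold change was 0.08, which was 0.04 under each of median centring, quantile and cyclic loess normalization and went from 0.03 without DMSO replicate 1 to 0.13 without DMSO replicate 2. They were TXNIP, the angiogenesis inhibitor VASH1 at 0.42 and the transcription factor KLF2 at 0.36, where VASH1 lost its call without DMSO replicate 1 or DZNep replicate 2 (limma adjusted p up to 0.364) and KLF2 without these or DZNep replicate 1 (up to 0.33) and under median centring (0.0676). The list shifted upward (camera adjusted p = 0.0315), and the call did not hold with the inter-gene correlation estimated (adjusted p = 0.473 with an estimated correlation), nor under quantile (0.0612) or cyclic loess (0.0536) normalization, nor without DMSO replicate 1 (0.077), nor by ranks (0.0689). The list was drawn up from memory of earlier work, which may include work on these samples, so it is not independent evidence of its direction. FBXO32, a ubiquitin ligase subunit, had a log2 fold change of 0.46 (limma adjusted p = 0.156), which was 0.78 without DMSO replicate 1 (adjusted p = 0.0066) and 0.14 without DMSO replicate 2 (0.352). The cell cycle inhibitor CDKN1A had one of −0.29 (limma adjusted p = 0.299), which was −0.52 without DMSO replicate 2 (adjusted p = 0.0335), −0.07 without DMSO replicate 1 (0.8) and −0.19 without DZNep replicate 1 (0.799).

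The integrated stress response list, the targets that ATF4 switches on under amino acid shortage and other stress, had the smallest camera p of the 35 lists. Of 35 genes measured, 27 fell and 1 rose (30 and 1 adjusted over the list alone), with a median log2 fold change of −0.95 (camera adjusted p = 4.38e-31, and adjusted p = 0.253 with an estimated correlation). Beside DDIT3, the mitochondrial folate enzyme ALDH1L2 fell 8.30-fold, the alanyl-tRNA synthetase AARS1 5.29-fold, the first enzyme of serine synthesis PHGDH 4.80-fold and the next one, PSAT1, 4.61-fold. The 1 member that rose was ATF4, at 0.36, named here after its value was seen, and its limma adjusted p of 0.047 went to between 0.067 and 0.488 when any 1 array was left out and to 0.0837 under median centring. Chaperones of the unfolded protein response fell as well. Of 20 genes, 17 fell and none rose (17 and 0 adjusted over the list alone), with a median of −1.30 (camera adjusted p = 2.52e-23, and adjusted p = 0.403 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, fell 4.18-fold, from 12.70 ± 0.18 to 10.63 ± 0.01 (SD, n = 2 arrays each), HYOU1 fell 5.02-fold, and the disulfide isomerase PDIA4 and the secreted factor CRELD2 had log2 fold changes of −2.06 and −1.94.

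The methionine and S-adenosylmethionine cycle list, which holds the target of the drug, had a median of −0.23 over 21 genes, with 7 lower and none higher (10 and 2 adjusted over the list alone). Its camera adjusted p was 3.1e-05 (adjusted p = 0.253 with an estimated correlation). The members that fell most were CTH, which makes cysteine from cystathionine, at −1.44, the folate enzymes MTHFD1 at −0.86 and SHMT2 at −0.85, and the spermine synthase SMS at −0.65. CTH also belongs to the stress response list.

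Most DNA replication genes and fewer of the mitotic genes fell, a difference that was not tested. Of 43 DNA replication genes, 31 fell and none rose (35 and 0 adjusted over the list alone), with a median of −0.59 (camera adjusted p = 2.94e-26, and adjusted p = 0.253 with an estimated correlation). The origin licensing factor CDC6 fell 3.28-fold, from 9.69 ± 0.07 to 7.98 ± 0.02 (SD, n = 2 arrays each), and the primase subunit PRIM1, the helicase factor CDC45 and the ribonucleotide reductase subunit RRM2 had log2 fold changes of −1.34, −1.31 and −1.17. Of 43 mitotic genes, 17 fell and none rose (28 and 0 adjusted over the list alone), with a median of −0.33 (camera adjusted p = 6.01e-14, and adjusted p = 0.473 with an estimated correlation). They included HMMR at −0.91, the spindle checkpoint genes MAD2L1 at −0.85 and BUB1 at −0.82, and the centriole kinase PLK4 at −0.76. Among 39 histone genes measured, 10 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.000241, and adjusted p = 0.473 with an estimated correlation). The median was 0.05 without DMSO replicate 1 and 0.24 without DMSO replicate 2. H2BC12 rose 3.22-fold and H4C4 by 0.81, while H3C1 had a log2 fold change of 0.76 (limma adjusted p = 0.0178, and 0.089 without DMSO replicate 1). The 1 that fell, H2AC13 at −0.39, was named after its value was seen. Its call (limma adjusted p = 0.046) ended when any 1 array was left out, with values from −0.30 to −0.48. It also ended under quantile (limma adjusted p = 0.0912) or cyclic loess (0.0729) normalization, where 9 histone genes rose and none fell. Histone genes are near-identical copies whose probes can bind one another's transcripts, so values of single members are uncertain.

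**Figure D3:**
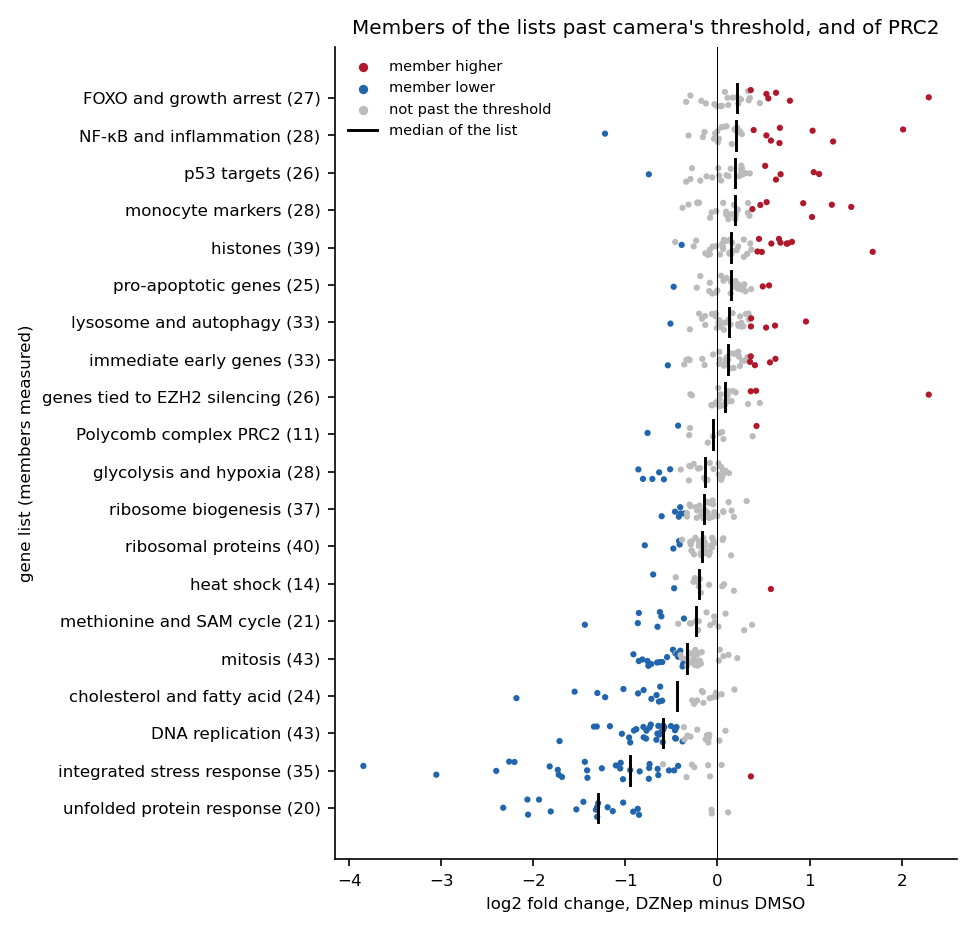
Each point is a measured member of a gene list, with its log2 fold change (DZNep minus DMSO) on the x axis; rows are the 19 lists past camera's threshold at the preset correlation, 0 of which passed with an estimated correlation (smallest adjusted p = 0.253), and the PRC2 list, ordered by their median, which a black bar marks. Members past the limma threshold are red or blue. The stress response and chaperone lists reach furthest left, with medians of −0.95 and −1.30.

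Few ribosome genes passed the test. Among 40 ribosomal protein genes, 4 fell and none rose (2 and 0 adjusted over the list alone), with a median of −0.17 (camera adjusted p = 6.92e-06, and adjusted p = 0.473 with an estimated correlation). RPL10 fell by 0.79 on the log2 scale, and RPL12, at −0.48, lost its call without DZNep replicate 1 (limma adjusted p = 0.108). Among 37 ribosome biogenesis genes, 6 fell and none rose (10 and 1 adjusted over the list alone), with a median of −0.15 (camera adjusted p = 0.000241, and adjusted p = 0.403 with an estimated correlation). The nucleolar helicase DDX21 had the largest fall, at −0.61. The ribosomal protein median was −0.10 under cyclic loess and the biogenesis median −0.09 under quantile normalization.

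Lipid synthesis genes under SREBP control fell in part. Of 24 genes of cholesterol and fatty acid synthesis, 12 fell and none rose (13 and 0 adjusted over the list alone), with a median of −0.44 (camera adjusted p = 1.48e-11, and adjusted p = 0.253 with an estimated correlation). The fatty acid desaturases FADS2, FADS1 and SCD had log2 fold changes of −2.18, −1.55 and −1.22, and the sterol carrier STARD4 one of −1.30. Of 28 glycolysis and hypoxia genes, 6 fell and none rose (7 and 0 adjusted over the list alone), with a median of −0.14 (camera adjusted p = 0.00103, and adjusted p = 0.473 with an estimated correlation). The median was −0.07 under quantile and −0.08 under cyclic loess normalization and −0.08 without DZNep replicate 1. PDK1, the kinase that holds back pyruvate oxidation, fell by 0.71 on the log2 scale, and the mitophagy receptor BNIP3, at −0.86, lost its call without DMSO replicate 1 (limma adjusted p = 0.099). Of 14 heat shock genes, 2 fell and 1 rose (3 and 1 adjusted over the list alone), with the mitochondrial chaperonin HSPD1 at −0.70 and the cochaperone DNAJA1 at 0.58. The heat shock median was −0.20 (camera adjusted p = 0.0253, and adjusted p = 0.403 with an estimated correlation), and this call also ended under quantile (0.0988) or cyclic loess (0.115) normalization, without the dimmest 25% of genes (0.087), and without DMSO replicate 1 (0.0576), DZNep replicate 1 (0.0818) or DZNep replicate 2 (0.133).

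Some monocyte markers rose, while a few granulocyte genes moved both ways. Of 28 monocyte and macrophage markers, 7 rose and none fell (9 and 1 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.000436, and adjusted p = 0.253 with an estimated correlation). The costimulatory receptor CD86 rose 2.74-fold, from 6.96 ± 0.12 to 8.41 ± 0.06 (SD, n = 2 arrays each), and S100A8, CD36 and TLR2 had log2 fold changes of 1.24, 1.03 and 0.93. Of 23 granulocyte genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone), CYBB, a subunit of the phagocyte oxidase, at 1.43 and the granule proteins BPI at −1.62, PRTN3 at −0.58 and CTSG at −0.61, the last call ending without DMSO replicate 1, where its value was −0.40 (limma adjusted p = 0.0504). This list did not shift (camera adjusted p = 0.828), and its median of 0.00 and mean of −0.01 differed in sign. Of 28 NF-κB and inflammation genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.000241, and adjusted p = 0.253 with an estimated correlation). TNF, the inhibitor NFKBIA at 1.26 and TNFAIP2 at 1.03 led the rises, and the chemokine CCL5 fell by 1.22 on the log2 scale. Among 33 immediate early genes, 5 rose and 1 fell (7 and 4 adjusted over the list alone), with KLF10 at 0.63 and FOSB at 0.57, and 2 rose under median centring. Their median was 0.12, or 0.18 without DZNep replicate 1 (camera adjusted p = 0.0324, and adjusted p = 0.473 with an estimated correlation), a call that ended without the dimmest 25% of genes (0.0518) and without DMSO replicate 2 (0.0856) or DZNep replicate 2 (0.28).

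Growth arrest, p53, lysosome and apoptosis lists each held a few rising genes. Of 27 FOXO and growth arrest genes, 6 rose and none fell (9 and 0 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.000118, and adjusted p = 0.253 with an estimated correlation). They included TXNIP, the transcriptional repressor BCL6 at 0.79, the antiproliferative BTG1 at 0.64 and PIK3IP1 at 0.55. Of 26 p53 targets, 5 rose and 1 fell (7 and 1 adjusted over the list alone), with ZMAT3 at 1.10, TP53INP1 at 1.05 and TRIAP1 at 0.69 against SESN2 at −0.75. SESN2 is also an ATF4 target of the stress list. The p53 median was 0.19 (camera adjusted p = 0.0062, and adjusted p = 0.473 with an estimated correlation), a call that ended without DMSO replicate 2 (0.149), and the median was 0.12 without DZNep replicate 2. Of 33 lysosome and autophagy genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone), with the lysosomal cathepsins CTSA at 0.96, CTSD at 0.62 and CTSB at 0.53, and 3 rose under median centring against 9 under quantile and 8 under cyclic loess normalization. Their median was 0.12 (camera adjusted p = 0.0062, and adjusted p = 0.587 with an estimated correlation), which was 0.19 under quantile normalization and 0.06 without DMSO replicate 2, and the call ended without DMSO replicate 2 (0.29) or DZNep replicate 2 (0.0854). Of 25 pro-apoptotic genes, 2 rose and 1 fell (3 and 1 adjusted over the list alone), with BMF at 0.56, a call that ended without DZNep replicate 2 (limma adjusted p = 0.114). Their median was 0.15 (camera adjusted p = 0.0324, and adjusted p = 0.403 with an estimated correlation), and the list call ended without DMSO replicate 2 (0.0749), DZNep replicate 1 (0.0773) or DZNep replicate 2 (0.0959). Of 11 anti-apoptotic genes, 1 rose and 1 fell (2 and 1 adjusted over the list alone), the caspase-8 inhibitor CFLAR at 1.04 and BCL2 at −0.47, the latter with a limma adjusted p of 0.149 without DZNep replicate 1. The other probe set of CFLAR had a log2 fold change of 0.41 and missed the threshold among all probe sets (limma adjusted p = 0.0602), and 3 members of this list rose under quantile normalization.

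Some genes of the leukemia program moved, in both directions. Of 18 genes, 4 rose and 2 fell (5 and 5 adjusted over the list alone), and 2 rose under median centring. FLT3, a receptor kinase that carries an activating internal duplication in MOLM-14, fell 1.92-fold, from 11.87 ± 0.10 to 10.92 ± 0.02 (SD, n = 2 arrays each, limma adjusted p = 0.00053), and the receptor kinase KIT and the transcription factor RUNX2 rose by 0.85 and 0.62. MEIS1, a cofactor of HOX proteins in leukemias with KMT2A rearrangements, had a log2 fold change of −0.27 (limma adjusted p = 0.112, and 0.032 with an intensity trend) and MYC one of −0.14 (adjusted p = 0.46, and values of −0.07 under quantile and −0.09 under cyclic loess normalization). HOXA9 has no named probe set here. The camera adjusted p of this list was 0.787, and its median of 0.01 turned to −0.02 under median centring.

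Markers of other cell types did not pass as lists in the fit of all 4 arrays. Camera gave an adjusted p of 0.343 for 15 B cell genes, 0.184 for 22 T and NK cell genes, 0.244 for 16 erythroid genes, 0.787 for 15 megakaryocyte genes and 0.285 for 19 fibroblast and epithelial genes. Without DMSO replicate 2 the erythroid (0.0419, median 0.21), T and NK cell (0.0465, median 0.17) and fibroblast and epithelial lists (0.0391, median 0.14) passed, and without DMSO replicate 1 their medians were −0.03, 0.00 and −0.06. No member of the B cell, T and NK cell and megakaryocyte lists passed the test over all genes or adjusted over the list alone. In the T and NK cell list GNLY had a log2 fold change of 0.42, which was 0.60 and passed without DMSO replicate 2 (limma adjusted p = 0.0116) and was 0.24 without DMSO replicate 1 (0.182), and CD4 one of 0.31, which passed under quantile (0.0238) or cyclic loess (0.0329) normalization, and in the B cell list PAX5 had −0.24. The values of GP6 and NFE2 in the megakaryocyte list were 0.26 and −0.23. Without DMSO replicate 1 the values of PAX5, GP6 and NFE2 were −0.39, 0.17 and −0.08, without DMSO replicate 2 they were −0.09, 0.35 and −0.38, and NFE2 had −0.14 without DZNep replicate 1 (limma adjusted p of 0.0508 to 0.909). Among erythroid genes 1 rose (1 adjusted over the list alone), the transferrin receptor TFRC, which dividing cells of many types express, at 0.44, a call that ended without either DZNep array (limma adjusted p of 0.107 and 0.121). Among fibroblast and epithelial genes 2 rose (2 adjusted over the list alone), MUC1 at 0.73 and DCN at 0.36, the latter call ending without DMSO replicate 1 or either DZNep array or under median centring (limma adjusted p of 0.0672 to 0.313). Of 31 interferon-induced genes, 1 rose and 2 fell (3 and 2 adjusted over the list alone), and 3 rose under quantile or cyclic loess normalization, with IFIT2 at 0.77 and the kinase EIF2AK2 at −0.50, whose call ended without DMSO replicate 1 (limma adjusted p = 0.0515) or DZNep replicate 1 (0.119). Of 37 oxidative phosphorylation genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone), with NDUFA2 at 0.51 (limma adjusted p = 0.0121, and 0.058 without DZNep replicate 1). Of 29 antioxidant genes, 2 rose and 2 fell (2 and 3 adjusted over the list alone), with the cystine transporter SLC7A11 at −0.84, TKT at −0.65, SOD2 at 0.62 and CAT at 0.57. Of 8 glucose-sensing genes, 1 rose, TXNIP, and none fell (2 and 0 adjusted over the list alone). The camera adjusted p was 0.271 for interferon, 0.285 for oxidative phosphorylation, 0.523 for antioxidant, 0.0942 for glucose-sensing and 0.119 for anti-apoptotic genes. Without DMSO replicate 1 the glucose-sensing (0.0186) and anti-apoptotic lists (0.0242) passed, the former also without DZNep replicate 1 (1e-04) or DZNep replicate 2 (0.001).

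Across the 35 lists camera with a preset correlation of 0.01 called 9 higher and 10 lower. With the correlation estimated per list, which rests on 2 residual degrees of freedom, camera called 0 lists, 6 at an unadjusted p of 0.05, while fry's directional test, which asks whether a list's genes move one way without comparing them with other genes, called 10, all in camera's direction.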

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

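Probe sets with no gene symbol or several were left out of the gene comparison and tested in a fit of all 28869 probe sets. Of 9559 such probe sets, 159 were higher and 129 lower with DZNep (limma adjusted p of 0.05), 102 of them with several symbols and 186 not listed in the annotation. The largest changes among those not listed were probe set 8021635, whose log2 intensity rose from 7.25 and 7.40 to 9.10 and 9.06, probe set 7982084, which rose from 4.79 and 4.79 to 6.06 and 6.53, and probe sets 7995362 and 8103834, which fell by 1.41 and 1.26 on the log2 scale. These 4 were chosen after their values were seen, and their genes are not named here.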

How the results depend on the processing

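No called gene named in the text and no called list changed direction under the alternatives that gave it a value, which leaves out treat and the crossed replicate block, run for gene counts only, and the dim filters for the genes they removed. Of 113 called genes that the naming rule gave, 77 kept their call whichever array was left out, 36 lost it without at least 1 array, 8 under at least 1 of the 3 other scalings, 20 with 16 subtracted before log2, an alternative chosen after seeing the data, and 24 when every probe set was tested. The median log2 fold change of all genes stayed between −0.01 and 0.03 under the scalings and the subtraction, and 28.2% to 40.7% of called genes were higher, against 35.1% in the reported fit.

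Without 1 array the count of higher genes ranged from 336 (without DZNep replicate 2) to 776 (without DMSO replicate 2) and of lower genes from 734 (without DZNep replicate 1) to 1662 (without DMSO replicate 2). Of 1892 calls, 1094 to 1648 were shared with these fits in the same direction. Without a DMSO array the spread rests on the DZNep arrays (SD of their log2 difference 0.14), and without a DZNep array on the DMSO arrays (0.20). Without a DZNep array, a common spread in effect served all genes, so calls there follow the size of the change alone. The counts therefore depend in part on which arrays set the spread, and how large that part is was not tested. Testing every probe set gave 89 at least 2-fold higher, since more features were tested. Limma's treat against a 1.5-fold change, a stricter test by construction, gave 37 higher and 73 lower. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry 4 higher and 6 lower. The robust hyperparameters were not run for lists, since camera has no such option, nor was the test of every probe set.

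Same-numbered arrays did not deviate together (the correlation across genes of their deviations from the group means was −0.22), so the numbers are not shown to pair the samples. The replicate block gave 754 genes higher and 1353 lower, 1826 of these 2107 calls shared with the reported fit, with 8 lists higher and 9 lower. The crossed replicate block, chosen after seeing the data, gave 1034 genes higher and 1690 lower. Signal over background limits dim genes, whose folds would be too small if a constant lies behind the deposited floor near 18, which was not tested. With 16 subtracted, 84 genes were at least 2-fold higher and 142 lower, against 59 and 121.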

Other observations

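The gene families and single genes here and in the next paragraph lie outside the fixed lists, were chosen after their values were seen and have no test as groups. Of 19 cytosolic tRNA synthetase genes, 16 fell and none rose, with a median log2 fold change of −0.59, and beside AARS1 the tryptophan and glycine enzymes WARS1 and GARS1 had −1.82 and −1.42. Of 34 amino acid transporters, 10 fell and none rose, with a median of −0.03 and the cationic amino acid transporters SLC7A1 and SLC7A2 at −1.72 and −1.55. Several of these genes also belong to the stress response list. Single genes that fell were IMPDH2, an enzyme of guanine nucleotide synthesis, at −1.26, ASS1, an enzyme of arginine synthesis, at −1.19, and the fatty acid receptor GPR84, at −1.42.

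Of 11 MHC class II genes and chaperones, 3 rose and none fell, HLA-DMB at 1.02, HLA-DMA at 0.77 and HLA-DQB1 at 0.57. Among single genes, the protease CTSK rose by 1.38, the gelatinase MMP2 by 1.21, osteopontin, SPP1, by 1.35, complement C3 by 1.15 and its receptor C3AR1 by 0.97. The growth factor TGFB2 rose by 1.39. In the ABCA lipid transporters 3 of 12 rose, ABCA9, ABCA6 at 1.43 and ABCA1 at 0.70, and 1 fell, and in the MS4A family MS4A6A rose while MS4A3, a gene of myeloid progenitors, had −1.03. HEXIM1, an inhibitor of the elongation factor P-TEFb, rose by 1.04. Of 176 microRNA genes with a probe set, 9 rose and none fell, among them MIR15B at 1.33, MIR181B1 at 1.04, MIR15A at 0.97 and MIR21 at 0.68.

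The 3 patterns below were weighed, and the tests of ARRDC4 and of small Cajal body RNAs were chosen only after the results were seen. Genes below outside the naming rule, such as ARRDC4, H2BC9, SNORD78, SNORD13 and SNORD13P3, and the small RNA families were likewise picked after their values were seen. The 1892 gene calls of the real split compare with at most 0 in either other split of the 4 arrays, so 1 of 3 splits gave as many, and 3 splits are too few for a share under 0.05. Each other split puts 1 DMSO and 1 DZNep array in each group, so the difference between treatments widens the spread within its groups. The 0 calls there therefore say little about chance.

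Most stress response and chaperone genes fell while TXNIP rose. DMSO replicate 1 lay furthest from the other arrays, but without it the median of the stress response list was −0.90, which argues against that array as the source. Depletion of glucose or other nutrients in the DMSO cultures could raise stress genes there and hold TXNIP down. ARRDC4, another target of the glucose-sensing factor MondoA, had a log2 fold change of 0.70 (SE 0.19, limma adjusted p = 0.0503). This lies between a rise of at least 1, taken here to mark depletion, and a value taken to speak against it. Both bounds were chosen after the results were seen, and ARRDC4 bears on glucose rather than on other nutrients. The value therefore cannot decide whether nutrients were depleted. The DMSO arrays differed for ARRDC4, at 6.85 and 6.13. Its log2 fold change was 1.06 without DMSO replicate 1 and 0.34 without DMSO replicate 2. Without DZNep replicate 1 and 2 it was 0.72 and 0.68. The value of 0.70 passed the test with an intensity trend (limma adjusted p = 0.0194, and 0.0296 with robust hyperparameters) and with array weights (0.0205). It also passed without the dimmest 25% of genes (0.0307) and by the mean over probe sets (0.0493). With the replicate block, whose numbers are not shown to pair the samples, the limma adjusted p was 4.67e-06. Under the 3 scalings it was 0.65 to 0.67 and did not pass (limma adjusted p of 0.063 to 0.121). An effect of the drug on the cells and a difference in culture state therefore cannot be told apart here, since each group holds only its own cultures.

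Of 39 histone genes 10 rose and 1 fell (9 and 0 under quantile or cyclic loess normalization) while 31 of 43 DNA replication genes fell, although histone mRNA is usually made with replication. Full cross-binding between histone paralogs would make members move alike. The gap between the highest and lowest H2B gene was 2.14, from H2BC12 at 1.69 to H2BC9 at −0.46 (SE 0.20 and 0.25). H2BC9 rests on DZNep replicate 2 and was 0.04 without it. The gap, then to H2BC14, was still 1.93, and it was at least 1.71 without any 1 array. The H2B probe sets therefore did not all read a single shared signal. Partial cross-binding from a rising gene could also leave a gap between the extreme members, so the gap cannot show how far cross-binding contributed. Histone genes known to make polyadenylated transcripts outside S phase may have risen, and the 6 measured had a median of 0.33 against 0.13 for the other 33, a difference of 0.19 (one-sided permutation p = 0.142), which leaves this open, as is an effect of the drug, which was not tested.

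Of 75 box C/D small nucleolar RNAs (snoRNAs) measured, 33 fell and 2 rose, with a median of −0.34 and SNORD78 at −1.76, while SNORD13 and its copy SNORD13P3 rose by 1.10 and 1.35. Lower recovery or labelling of small RNA with DZNep could account for a general fall. The 39 bright box C/D snoRNAs outside the hosts GAS5 and SNHG1, with the SNORD115 and SNORD116 families left out, had a median of −0.30. This barely met a bound of −0.3 (−0.3005). The bound was set before this median was taken but after snoRNAs were seen to fall, so it is not an independent test. Of 61 H/ACA snoRNAs 9 fell and 1 rose with a median of −0.10, and of 16 small Cajal body RNAs 3 rose and none fell with a median of 0.12. The 9 bright ones among the latter had a median of 0.36, above the 39 bright snoRNAs by 0.66 (two-sided permutation p = 0.0017). The permutation shuffled RNAs measured on the same arrays, so its p does not measure the spread between samples. On these arrays the small Cajal body RNAs and box C/D snoRNAs did not change alike, which an equal loss alone would not give. A loss that differs between kinds of small RNA stays open. The 9 snoRNAs from GAS5 and SNHG1, hosts picked after some of their snoRNAs were seen to fall, had a median of −1.34, which lower host transcripts may explain, but the hosts have no named probe set here.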
